A study of Mus musculus with 6 samples.

How the data were processed

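RNA was measured in 6 hippocampus samples of male mice, 3 from a group treated with an amyloid-β fragment (Aβ25-35), named AD by the labels, and 3 controls. Each sample was hybridised alone, with Cy3, to an Agilent array for long non-coding RNA, per the labels. Scanner images were read with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. The background correction, the normalization tool, the filter on probes and the log base are not given in the sources used here.

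The values used are the log2 intensities that the authors deposited as 1 table of 100337 probes by 6 arrays. That they are log2 is inferred from their range, 1.09 to 18.7, which is too high for natural logs of scanner brightness. The table behaves as quantile-normalized. The 602022 values are drawn from 117288 distinct numbers, of which 58443 occur exactly 6 times among all values, and arrays differed by at most 0.142 at any rank. Quantile normalization gives every array the same distribution, so a shift of most transcripts in one direction would not be visible. The table holds no background or detection flags, and the number of arrays limits the precision.

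The table does not pair probe IDs with genes, and 0 of the IDs matched the mouse gene tables used here. Tests of single genes, of non-coding genes and of 49 gene lists (cell type markers, synaptic, inflammatory, stress and metabolic genes) had been fixed before the data were examined and are not reported, because no probe could be given a gene. No genome position is given for the same reason. Each ID holds a run of letters, which sorts the probes into 9 classes. The letters are not explained in the sources used here and are used only as names. The classes were chosen after the IDs had been seen.

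The AD and control groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term, 4 residual degrees of freedom), on the values as deposited and with no filter. P-values were adjusted by the Benjamini-Hochberg method over all probes, with a threshold of 0.05. Intervals are 95% intervals of the moderated fit. A second count, fixed beforehand as a description and not a call, took probes with at least a 2-fold difference and an unadjusted p under 0.05. Class means per array were compared by exact permutation of the 6 arrays (two-sided), adjusted over the 8 classes with at least 100 probes. With 3 arrays against 3 this exact permutation test cannot go below p = 0.1. A rule fixed beforehand was to name up to 10 genes in each direction. With no gene names, it was adapted afterwards to probes. Probes past the threshold came first, and places left were filled by the smallest p among probes above the median level whose groups did not overlap. Since no ID has a gene name, only the first 2 in each direction are printed.

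Simulated arrays had each probe's real mean and estimated spread within groups, with normal noise drawn independently for each probe. On these arrays 100 probes changed by 1 and 100 by 2 on the log2 scale were added to the AD against control comparison over 100337 probes. The test recovered 27 of those changed by 1 and 66 of those changed by 2, and 6 of 99 calls were false. Above the median level it recovered 18 of 48 changed by 1 and 43 of 50 changed by 2. Real probes did not vary independently. The spreads are estimates from few arrays and include any shared difference between arrays of a group. These rates may therefore differ on the real arrays.

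The replicate numbers 1 to 3 occur in both groups. Same-numbered arrays did not deviate together, so the fit without a replicate block was kept. Alternatives were the replicate block, quantile normalization, centring on the 75th percentile or the median, removal of the dimmest 25% or of all probes at or below the median level, an intensity trend with robust variances, array weights, and leaving out each array. Cyclic loess was added after the data had been seen. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. Slide, scan and day were not used here.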

Results

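The data were array profiles of the mouse hippocampus, a brain region needed for memory, in a model of Alzheimer disease. The model group (AD) was made with Aβ25-35, a short neurotoxic fragment of the amyloid-β peptide, and was compared with control mice. Each group held 3 arrays, all from males labelled day 28, with no statement of what the day counts from. Each array gave a log2 intensity for 100337 probes. The median intensity lay between 6.99 and 7.01 on every array and the 75th percentile was 9.69 or 9.70. The 25th percentile was 3.59 and 3.61 on AD replicates 1 and 2, 3.53 on AD replicate 3, and 3.56 on each control. Probes have no gene names here, so results are given by probe ID and by the letters in the ID.

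The first question was how far the arrays followed their groups. The 3 control arrays had the highest mean correlation, 0.9918, with Pearson correlations across probes of 0.9914 to 0.9922. AD replicates 1 and 2 also resembled each other, at 0.9903, and stood apart from the controls, at 0.9868 to 0.9883. AD replicate 3 did not lie with them. Its correlations with the controls were 0.9907 to 0.9918, and those with AD replicates 1 and 2 were 0.9858 and 0.9859. The root mean square difference was 0.509 log2 units between AD replicate 3 and a control, on average, against 0.648 between AD replicate 3 and AD replicates 1 and 2, and 0.493 between controls. Among probes above the median level AD replicates 1 and 2 correlated at 0.9938 with each other, above every pair of controls, which gave 0.9917 to 0.9936. AD replicate 3 again correlated more with the controls, at 0.9902 to 0.9920, than with the other AD arrays, at 0.9879 to 0.9894. Among these probes AD replicates 1 and 2 correlated with the controls at 0.9889 to 0.9907, a range that overlaps that of AD replicate 3. The first principal component took 36.1% of the variance between arrays. It placed AD replicates 1 and 2 on one side, at 0.61 and 0.53, and AD replicate 3 at -0.39 on the side of the controls, which lay between -0.29 and -0.23. These correlations are across probes, which are not independent replicates.

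**Figure D1:**
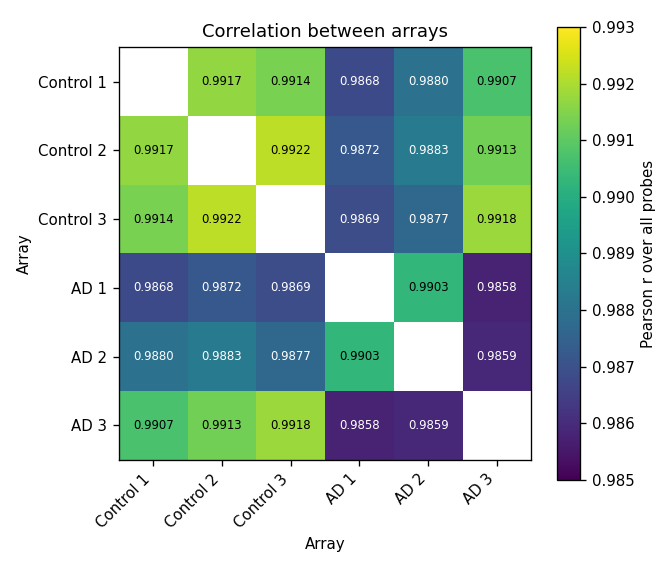
Pearson correlation between each pair of the 6 arrays over all 100337 probes (colour and printed value, both axes list the arrays). AD 1 and AD 2 correlate at 0.9903 with each other, and AD 3 at 0.9907 to 0.9918 with the controls but at 0.9858 and 0.9859 with AD 1 and AD 2.

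The main comparison asked which transcripts differ in the hippocampus between the Aβ25-35 group and controls. With limma and Benjamini-Hochberg adjustment, 0 of 100337 probes passed an adjusted p of 0.05, and the smallest adjusted p was 0.212. At an unadjusted p under 0.05 there were 7465 probes, 7.44% of the total, against a nominal 5017. Of the 9 other splits of the 6 arrays into 3 and 3, 2 gave more, 8776 and 9012, and the others gave 2019 to 6901. The values of the groups did not overlap for 15794 probes, or 15.7%, against 10% by chance for 3 arrays against 3. That 10% is an average over all splits into 3 and 3. Non-overlap was not counted for the other splits, so the excess cannot be tied to the group label. The group differences, with AD replicate 3 included in the AD mean, were small among brighter probes. Among the 50168 probes above the median level, the median absolute difference was 0.087 log2 units and the median half-width of the 95% interval was 0.246. For 48111 of these probes, or 95.9%, the interval excluded a 2-fold difference in either direction. Below the median level the interval excluded it for 53.5% of probes. Leaving out AD replicate 3 raised the number of probes past the threshold from 0 to 697, of which 172 were higher and 525 lower in AD replicates 1 and 2. Leaving out any other array gave 0 to 6.

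Named probes had to lie above the median level with groups that did not overlap, and the 2 of smallest p among those higher in the AD group did not pass the threshold. Probe mmu_bmr027618 had a log2 intensity of 8.63 ± 0.02 (SD, n = 3) in the AD group and 8.11 ± 0.12 (SD, n = 3) in controls. Its log2 difference was 0.52 with a standard error of 0.08 (limma adjusted p = 0.523), a 1.43-fold difference. Probe mmu_gmr066914 had 8.49 ± 0.03 (SD, n = 3) against 8.14 ± 0.01 (SD, n = 3), a 1.28-fold difference (limma adjusted p = 0.536). The 2 lower probes named by the same rule had larger differences but did not pass either. Probe mmu_bmr027429, one of the bright probes, had 12.46 ± 0.10 (SD, n = 3) in the AD group against 13.30 ± 0.02 (SD, n = 3), a log2 difference of -0.84 with a standard error of 0.08 (limma adjusted p = 0.243). Probe mmu_gmr055749 had 6.91 ± 0.08 (SD, n = 3) against 7.72 ± 0.06 (SD, n = 3), a log2 difference of -0.81 (limma adjusted p = 0.243). On these 4 probes AD replicate 3 lay on the side of AD replicates 1 and 2, as the rule for naming them requires. Without AD replicate 3 both lower probes passed, with limma adjusted p of 0.033 for mmu_bmr027429 and 0.047 for mmu_gmr055749.

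**Figure D2:**
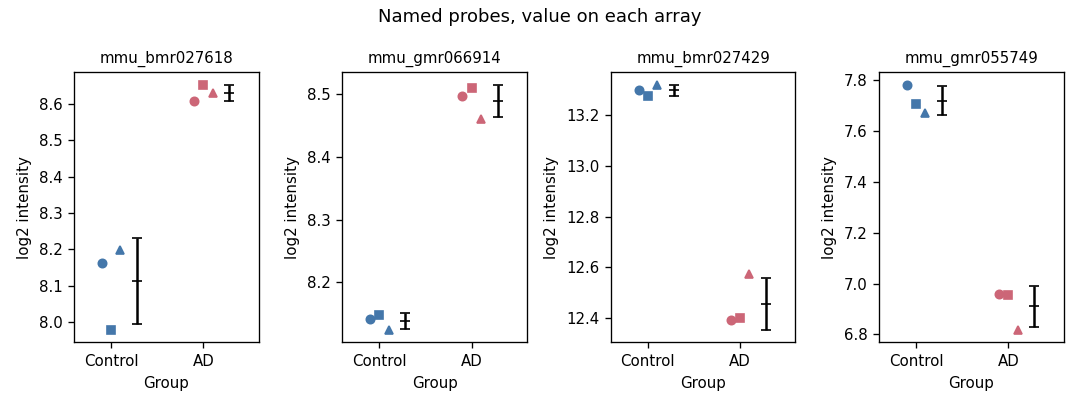
Log2 intensity (vertical axis) of the 4 named probes on each array, by group (horizontal axis). Circles, squares and triangles are replicates 1, 2 and 3, and the bars are the mean ± SD of 3 arrays. The groups do not overlap on any of the 4 probes, and each axis covers only the range of its values.

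A 2-fold difference with an unadjusted p under 0.05, given only as a description, was met by 1078 probes, 487 higher and 591 lower in the AD group. Of these, 1027, or 95.3%, lay at or below the median level and 51 above it. The spread between replicates differed with level. When probes were ranked into 10 bins by level, the median SD within groups was 0.134 log2 units in bin 1, the dimmest, rose to 0.632 in bin 2 and fell from there to 0.088 in bin 10. Bin 1 held 0 of the 1078 probes, bin 2 held 505 and bin 10 held 0. Without AD replicate 3 the count was 3591, against 1020 to 1191 without any other array.

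**Figure D3:**
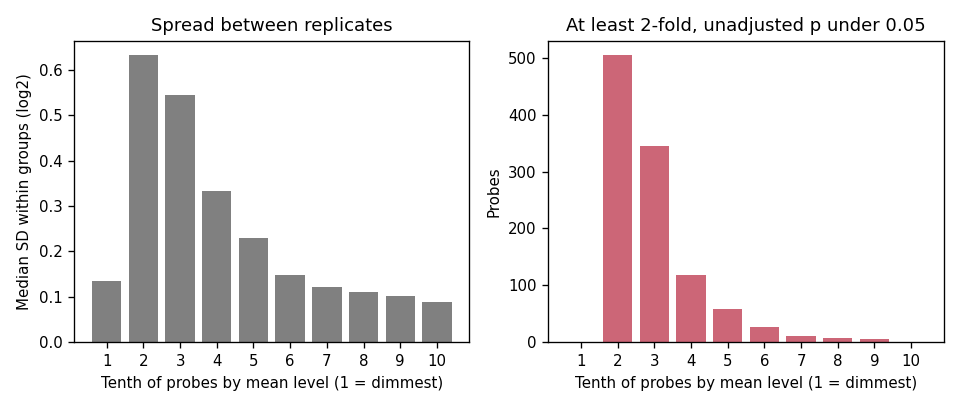
Probes ranked into 10 bins by their mean log2 intensity over 6 arrays (horizontal axes, bin 1 dimmest). The bars show the median SD within groups in log2 units on the left, and on the right the number of probes with at least a 2-fold difference and an unadjusted p under 0.05, which is 0 in bin 1 and falls from 505 in bin 2 to 0 in bin 10.

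Each class of probe ID was compared between the groups, and not with other classes, since intensity also depends on each probe's binding and background. Class gmr held 60164 probes, bmr 11008, gnc 10912, bnc 9222, gmi 6081, gci 1687, bmi 1123 and bpr 139, and class brr, with 1 probe, was not tested. In class gmr the mean was 8.25 ± 0.03 (SD, n = 3) in the AD group and 8.217 ± 0.006 (SD, n = 3) in controls. Class bnc had 3.61 ± 0.04 (SD, n = 3) against 3.67 ± 0.02 (SD, n = 3), a difference of -0.06 (exact permutation p = 0.1, the smallest the design allows, and 0.267 adjusted over 8 classes). Classes bmr and bpr also reached an exact permutation p of 0.1, with differences of -0.03 and -0.06. The other 5 classes had exact permutation p-values of 0.3 to 0.8 and differences between -0.05 and 0.03. No class passed after adjustment. When probes were adjusted over their class alone, 2 gnc probes and 1 bmi probe passed, with limma adjusted p of 0.035, 0.035 and 0.012. Their log2 differences were 1.64, -1.22 and -0.96, and their mean levels of 2.12, 1.81 and 1.81 lay close to the lowest value of the table, 1.09. These 3 probes were singled out after their values had been seen.

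**Figure D4:**
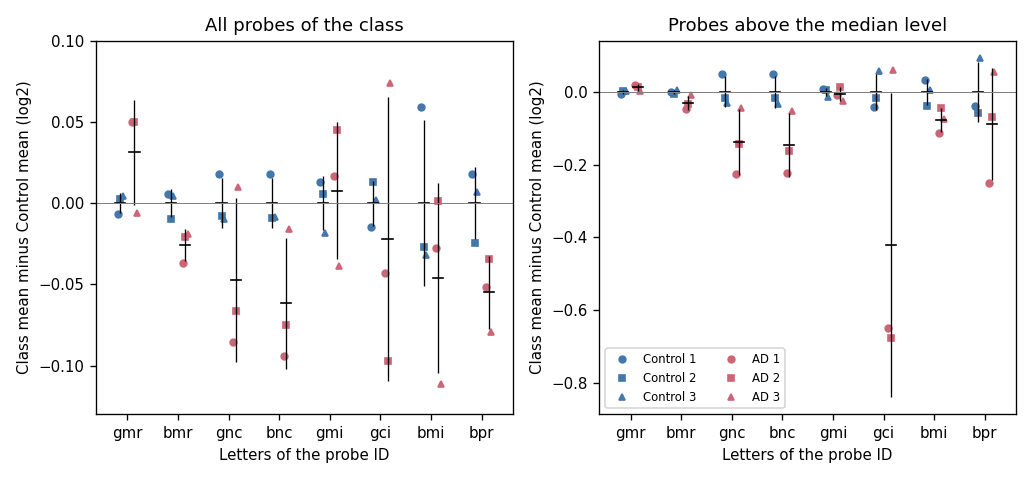
Mean log2 intensity of each of 8 classes of probe ID (horizontal axes) on each array, minus the mean of the controls (vertical axes), for all probes and for those above the median level. Points are arrays, black lines the mean ± SD of 3 arrays, and the 2 panels have different scales. In class gci above the median level, AD 1 and AD 2 lie at -0.65 and -0.68 and AD 3 at 0.06.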

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

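With 0 probes past the adjusted p of 0.05 in limma, the count was also 0 under the replicate block, quantile normalization, both centrings, cyclic loess, both filters on dim probes, the trended robust variances and array weights. Leaving out 1 array gave 0 to 697 probes, with 697 without AD replicate 3, 6 without control replicate 3 and 2 without control replicate 1. At an unadjusted p under 0.05 the count was 7465 as deposited, 6263 with the replicate block and 15746 with array weights, which gave AD replicate 3 a weight of 0.345 against 0.886 to 1.61 for the other arrays. That count was 18655 without AD replicate 3, and 5012 to 6297 without any other array. Same-numbered arrays shared only a number: their deviations from the group means correlated at 0.0097, 0.013 and 0.062, and not every array correlated best with its own number. The count of probes with at least a 2-fold difference was 1103 with the replicate block and 2701 with array weights, against 1078 as deposited. With the fit rerun on the remaining probes, it was 370 without the dimmest 25% of probes and 86 for probes above the median level. The fit over all probes gave 51 above the median level. Leaving out 1 array moved it between 1020 and 3591. Cyclic loess, added after the data had been seen, made 424 of 1090 probes higher, against 487 of 1078. It moved the class means by more than 1 SD in bmr (-0.054), gnc (-0.0863), bnc (-0.10) and bpr (-0.0941), where the cause was not tested. Without the dimmest 25% of probes the class differences were -0.0948 for gnc, -0.12 for bnc, -0.26 for gci and -0.13 for bpr. Above the median level they were -0.14, -0.15, -0.42 and -0.0882. Fewer and brighter probes entered these means, and why the differences changed was not tested. Leaving out 1 of 3 arrays cannot move a class mean past 1 SD, so this is no test. Still, 5 classes changed over 1.5 times, each with 1 end without AD replicate 3. Ranges were gmr 0.022 to 0.050, gnc -0.076 to -0.028, bmi -0.070 to -0.013, gci -0.070 to 0.016 and gmi -0.011 to 0.031. Classes gci and gmi have no settled direction. The adjusted p of the 4 named probes ran from 0.033 to 0.815 over the alternatives. Their direction under left-out arrays was fixed by the rule that chose them. Results for genes, non-coding genes and gene lists were not run under any setting, since no probe has a gene name. Signal over background could not be judged without flags.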

Other observations

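Apart from the 3 by 3 splits for probes past the threshold and the fit without AD replicate 3, the tests in this part were chosen after the data had been seen. For cyclic loess and the 5-array splits this was before their own outcome was known. The fit without AD replicate 3 belonged to the planned fits that each left out an array, but that array was singled out after the arrays had been compared. Brighter probes of the class gci stood apart on AD replicates 1 and 2. This class held 60 probes above the median level, singled out after their values were seen. Their mean log2 intensity differed from the control mean by -0.65 on AD replicate 1, by -0.68 on AD replicate 2 and by 0.06 on AD replicate 3, against -0.04, -0.02 and 0.06 on the 3 controls. Of the 60 probes, 54 were lower in AD replicates 1 and 2 than in controls, and 20 were lower on AD replicate 3. The group difference of -0.42 had an exact permutation p of 0.4. In 4 of the 8 classes, gnc, bnc, bmr and bmi, all 3 AD arrays lay below all 3 controls over probes above the median level (910, 937, 4276 and 271 probes). Class gnc differed by -0.22, -0.14 and -0.04 on AD replicates 1, 2 and 3, bnc by -0.22, -0.16 and -0.05, bmr by -0.046, -0.034 and -0.0083, and bmi by -0.11, -0.044 and -0.075 (exact permutation p = 0.1 for each, the smallest possible, and 0.2 adjusted over 8 classes). On AD replicate 3, 474 of the 910 gnc, 498 of the 937 bnc, 1984 of the 4276 bmr and 155 of the 271 bmi probes were lower than the control mean. Over all probes of the class, the separation held for bmr and bnc but not for gnc (exact permutation p = 0.3) or bmi (exact permutation p = 0.5). The arrays share nearly the same distribution, so class means are coupled and lower means in some classes must be balanced elsewhere. Class gmr, with 40436 probes above the median level, differed by 0.012 the other way. The separations of the 4 classes are therefore not independent results.

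Without AD replicate 3, 697 probes passed the threshold, 525 lower and 172 higher in AD replicates 1 and 2, with a median size of 1.28 log2 units. Of these, 171 lay above the median level. By class there were 218 gmr, 136 gnc, 133 bmr, 132 bnc, 34 gci, 28 gmi, 14 bmi and 2 bpr probes. This is 0.362% of gmr probes, 0.460% of gmi probes and 2.02% of gci probes. In bmr, gnc, bnc, bmi and bpr the share was 1.21% to 1.44%. The shares were not tested against each other, since the classes differ in level.

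The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For probes past the threshold all 10 splits gave at least the real count of 0, and the highest other count was 6. For the 2-fold count 4 of the 10 splits, the real one included, gave at least 1078, and the highest other was 1697. The 3 other splits that exceeded it were those that put AD replicates 1 and 2 with 1 control and AD replicate 3 with the other 2, so the count follows a structure of the samples that the groups do not describe. Without AD replicate 3, 1 of 10 splits of the other 5 arrays into 2 and 3, the real one, gave 697 probes, and the highest other gave 6. The correlations had already set AD replicates 1 and 2 apart from all other arrays. With AD replicate 3 removed, this split was thus likely to stand out, and the count is no test of the group label.

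The pattern that most changes the comparison is that AD replicate 3 lay with the controls. A swap of labels between the groups is argued against, since the highest correlation of any control with AD replicate 1 or 2 was 0.9883, below the lowest between controls, 0.9914. As the source of this pattern, an intensity-dependent bias of the kind that cyclic loess removes is argued against as well. The gap between the mean correlations of AD replicate 3 with controls and with the other AD arrays was 0.0054 as deposited and 0.0054 after cyclic loess. Cyclic loess did move some class means, so the arrays may still carry such a bias. Noise of single spots alone is also argued against. Above the median level the difference of AD replicate 3 from AD replicates 1 and 2 correlated at 0.482 between probes with consecutive ID numbers. The highest of 100 shuffles was 0.012, and at or below the median level the correlation was 0.210. The difference of control replicate 1 from the other controls also gave 0.319 above the median level, so this is not particular to AD replicate 3. A weaker response in the same direction was tested on the 697 probes of smallest p between AD replicates 1 and 2 and 2 controls, a different set for each control left out, with AD replicate 3 set against that control. These sets are rankings, since the 3 fits put only 2, 0 and 0 probes past the adjusted threshold. For lower probes the signed median was -0.20 to -0.10 over the 3 choices, away from the response, and for higher probes -0.032 to 0.023. Yet over gnc, bnc, bmr and bmi probes above the median level, the mean of AD replicate 3 lay below all 3 controls, as on AD replicates 1 and 2. A weaker response therefore stays open for lower and higher probes. A single wrong label, a sample from outside the 2 groups, arrays handled apart, or an animal that differed for biological reasons cannot be told apart, because no batch label or gene name bears on the 697 probes gained without that array.

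Probes with consecutive ID numbers moved together, less so among dim probes. Above the median level the AD minus control difference correlated at 0.407 between consecutive IDs over 36972 pairs, at 0.019 between IDs 50 apart, and at most at 0.011 in 100 shuffles. At or below the median level it correlated at 0.167 between consecutive IDs. The difference of control replicate 1 from the other controls correlated at 0.319 above the median level and 0.099 at or below it. One candidate explanation is that consecutive IDs are probes of the same or neighbouring transcripts, which would make part of the variation between arrays, within groups as well as between them, a property of the samples and not of single spots. The table does not say what the numbers stand for, and this was not tested further.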
